A study of Populus tremula x Populus alba with 3 samples.

How the data were processed

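Apical buds of WT and of the RNA interference lines KD2 and KD5 were sampled as pools of 15 buds from 15 plants each, and genomic DNA was sequenced after bisulfite treatment on an Illumina instrument, per the labels' protocols. Per the submitters' processing notes, Bismark and methylKit were used; versions, filters, coverage minimum and genome build are not given in the sources used here. The gene models carry a Phytozome tag in the file contents, and coordinates are printed as the deposited tables give them. The values used here were 6 tables of the authors' own comparisons, 3 for promoters and 3 for transcribed regions, and no value per library was used. Sequencing depth is unknown.

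Methylation differences in the promoter tables are in percentage points, 1 value for KD2 and 1 for KD5, deposited by the authors. All of them are negative although the title lines call the regions hypermethylated in the knockdowns, so they were read as WT minus knockdown and the sign was turned, giving gains. The transcribed region tables give gene and feature coordinates but no methylation difference and no region coordinates. The authors deposited an expression logFC and a logCPM per gene, read here as log2 values; the headers give neither the log base nor the direction, and the libraries behind them are not among the 3 samples. Per the file headers the tables also hold a p-value and an FDR for expression, and all listed FDR values are below 0.05. The column names are those of an edgeR result table as deposited by the authors, but the program is not stated. The tables hold no p-value of a methylated region.

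Each row was taken as 1 gene, and each gene once within a table. Counts and shares used exact Clopper-Pearson 95% intervals. Medians of gains have percentile bootstrap intervals from 10000 resamples of promoters, and differences of medians and correlations were tested by two-sided permutation with 100000 resamples. Signs of logFC were compared by two-sided Fisher's exact tests, leaving genes of both sets out of both. Benjamini-Hochberg adjustment was applied within families of 6 gain comparisons, 3 line correlations, 6 gain to expression relations, 10 sign comparisons, 12 feature comparisons and 14 gene lists. The shared WT was simulated as normal noise in 3 libraries, keeping items with both gains above the smallest in the table, with the noise set so that the median gain matched.

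Gene lists, the main comparisons and most other settings were fixed before the data were examined. Comparisons by expression level and gene length, tests of lists within logCPM quintiles, groups of annotation words and the settings named as such below were added after the data were seen. A gene joined any of 18 lists by its Arabidopsis locus or by words of its annotation in the tables, so some genes are in several, and 14 lists held at least 1 gene. Named genes were, per direction, the 12 promoter genes and 10 transcribed region genes with the largest absolute logFC, up to 10 genes in all 3 contexts, up to 4 members per list, and any gene of the DNA methylation list. List members are those with the largest absolute logFC. Where a gene falls under several of these it is described once. Genes outside this rule were named after their values were seen, for an extreme gain, an exception to a list's sign, a mismatch with a list, a word group or the rest of the meristem list. Of the genes this rule picks, 1 is not reported here.

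Alternatives were a gain of at least 1.5 times the smallest in the table in both lines, merged overlapping windows, means for medians, an absolute logFC of at least 1, absolute logFC in the correlations, genes of both sets counted in each, and lists from Arabidopsis loci alone. Chosen after seeing the data were an FDR below 0.005, lists without 4 members matched by letters, promoters on the chromosome of their identifier, and promoters without gains of 80 points or more. A stricter p of the region, expression in KD2 or KD5 alone and overlap of regions between contexts were not run, since the tables used here hold no such values.

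The tests were checked on simulated data. For a list of 42 of 577 genes, Fisher's exact test fell below 0.05 in 2% of 200 simulations with no difference and in 100% with a list made 90 percent negative. Where the sign followed expression alone, the test within logCPM quintiles fell below 0.05 in 4.50% of simulations, and Fisher's exact test in 99%. For 49 promoters, the rank correlation test fell below 0.05 in 8.50% of 200 simulations with no relation, and in 4.60% of 1000 after their number was raised for this reason. The test of a difference of medians did so in 8% of 200 simulations with no difference, in 4.60% of 1000 run later, and in 90.5% with a planted shift of 6 points. That shift also raised the smallest gain of the shifted set, whereas the listed contexts share a minimum near 15 points. The 90.5% is therefore not the power to find such a difference among the listed gains. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.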

Results

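The material was apical buds of the hybrid poplar Populus tremula x Populus alba, a laboratory clone widely used for genetic transformation. Wild type plants (WT) were compared with 2 RNA interference lines, KD2 and KD5, in which PtaDML10 is the target. PtaDML10 belongs to the DEMETER-like family, DNA glycosylases that remove 5-methylcytosine. Plants spent 4 weeks in long days of 16 h light at 21 °C, then 12 weeks in short days of 8 h light at 19 °C, then 4 weeks in short days at 4 °C. From 15 plants per genotype, 15 apical buds were taken before visible bud break, and each genotype gave 1 whole genome bisulfite library, a library in which unmethylated cytosines read as thymines. With 3 libraries and no replicates, no difference between a knockdown and WT has a replicate check, and no p-value is given for it.

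The values came from the authors' own comparisons, as 6 lists of genes that were both hypermethylated in the knockdowns and changed in expression. The lists split by gene part (promoter or transcribed region) and by sequence context (CG, CHG or CHH, where H is A, C or T). Sequencing depth and coverage per region are unknown, so the precision of a single methylation gain cannot be stated. Intervals below are exact Clopper-Pearson 95% intervals and cover counting error only, and genes or promoters are not independent replicates. Expression is a logFC, 1 value per gene for both lines together. Its log base and its direction are not stated in the tables, so genes are described as having a positive or negative logFC, not as induced or repressed. PtaDML10 itself is not among the genes analysed here, so its own level could not be used to check the labels or to settle the direction.

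The lists answer which genes both gained methylation and changed expression in the DML10 knockdowns. In all, 577 distinct genes were listed, 524 for the transcribed region, 83 for the promoter and 30 for both. CG regions were the most frequent, with 388 genes in the transcribed region and 49 in the promoter. CHG regions followed with 178 and 30 genes, and CHH regions with 123 and 21 genes. The cellulose synthase-like gene CSLD3 (Potri.001G136200), whose Arabidopsis counterpart is needed for root hair tip growth, was the only gene present in all 6 lists. Because the tables hold only genes that passed the authors' thresholds for both methylation and expression, these counts do not give the share of all genes that changed. Requiring a gain of at least 1.5 times the smallest in the table in both lines left 17 of the 83 promoter genes.

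**Figure D1:**
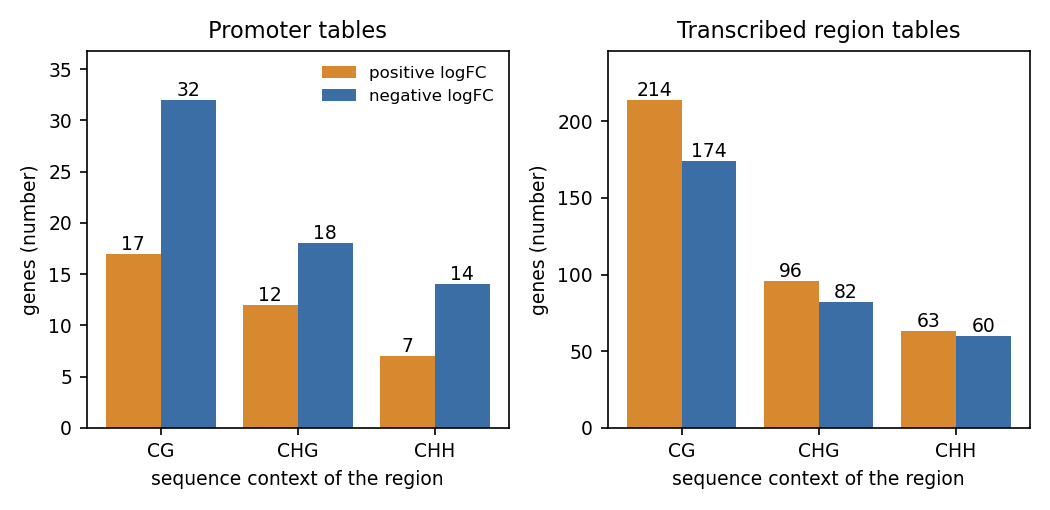
Number of genes (vertical axis) by sequence context (horizontal axis) in the promoter tables (left) and the transcribed region tables (right), with orange bars for a positive and blue bars for a negative logFC. Promoter genes with a negative logFC outnumber those with a positive logFC in each context (32 against 17 in CG), while in the transcribed region the positive genes are slightly more numerous (214 against 174 in CG).

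Promoters gained methylation in both lines, by medians of about 19 to 26 percentage points. In CG, the median gain was 19.4 points in KD2 (bootstrap 95% interval over promoters 17.5 to 21.9) and 25.6 points in KD5 (22.3 to 31.1). In CHG it was 18.9 points in KD2 (17.4 to 20.2) and 21.8 points in KD5 (19.6 to 25.9). In CHH it was 20.0 points in KD2 (18.1 to 22.9) and 20.0 points in KD5 (17.1 to 30). The smallest gain was 15 points in CG, 15.1 points in CHG and 15.1 points in CHH, so the medians describe the part of a distribution above a threshold. No pair of contexts differed in median gain past the threshold in either line. The largest difference, CG against CHH in KD5, was 5.62 points (two-sided permutation p = 0.237, Benjamini-Hochberg adjusted p = 0.710 over 6 comparisons). Promoters listed in both contexts of a pair were counted in each.

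A few promoters stood far above these medians in at least 1 line. The largest CG gain in the authors' deposited tables belonged to the promoter of Potri.001G149800 (chromosome 1, 12336746 to 12338745), at 92 points in KD2 and 100 points in KD5, with a logFC of -0.69. The promoter of calnexin 1 (Potri.012G111100, chromosome 12, 13294953 to 13296952), an endoplasmic reticulum chaperone, had a CHH gain of 80 points in KD2 but 15.4 points in KD5 in the authors' deposited tables. In the authors' deposited tables, CG gains near 60 points in KD5 alone were listed for Potri.001G053700 (61.0 points, 27.1 points in KD2), a zinc-binding dehydrogenase family gene (Potri.001G391100, 60.0 points, 19.4 points in KD2) and Potri.005G221800 (60.9 points, 20.0 points in KD2). These promoters were picked for their gains after the values were seen.

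KD5 gained more than KD2 at CG promoters. The gain was larger in KD5 at 38 of 49 CG promoters (77.6%, 63.4 to 88.2), with a median excess of 6.25 points (bootstrap interval 2.64 to 8.56). At CHG promoters it was larger in KD5 at 18 of 30 (60.0%, 40.6 to 77.3), and at CHH promoters at 11 of 21 (52.4%, 29.8 to 74.3), intervals that include an even split. Since each line is 1 library, this compares those libraries.

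By rank, the gain in KD2 and that in KD5 were not related past the adjusted threshold in any context. In CG, Pearson's r was 0.65 (permutation p = 0.00208, adjusted 0.00624 over 3 contexts) and Spearman's rho was 0.33 (permutation p = 0.0208, adjusted 0.0623). Without the 2 promoters farthest from the KD2 median r was 0.25, so the linear relation rested on them. In CHG r was 0.34 (permutation p = 0.0630) and rho 0.02 (permutation p = 0.911), and in CHH r was -0.23 (permutation p = 0.338) and rho -0.39 (permutation p = 0.0819). Without the 2 farthest promoters r was -0.06 in CHG and 0.19 in CHH, and rho in CHH was -0.19 (permutation p = 0.434). Over promoters on the chromosome of their identifier, a filter chosen after seeing the data, rho was 0.39 in CG (permutation, adjusted p = 0.0275) and -0.51 in CHH (permutation, adjusted p = 0.0416). Without gains of 80 points or more, also chosen afterwards, rho was 0.29 in CG (permutation, adjusted p = 0.147) and -0.30 in CHH (permutation, adjusted p = 0.300). Both lines share the WT library. Simulated unchanged lines against 1 shared WT with the same minimum gain gave r = 0.16 in CG, 0.15 in CHG and 0.15 in CHH. That simulation gave every promoter the same normal noise, whereas methylation percentages are bounded and depth is unknown, so it is a rough guide only. The covariance in CG was 115 against a simulated 8.04, in CHG 19.1 against 3.41 and in CHH -25.1 against 3.4. The CG and CHH values each include a promoter with a gain of 80 points or more, and covariance was not computed without it. They therefore cannot show an excess shared by most promoters. With 1 WT library no split of the controls was possible, so part of any excess may come from the shared WT.

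**Figure D2:**
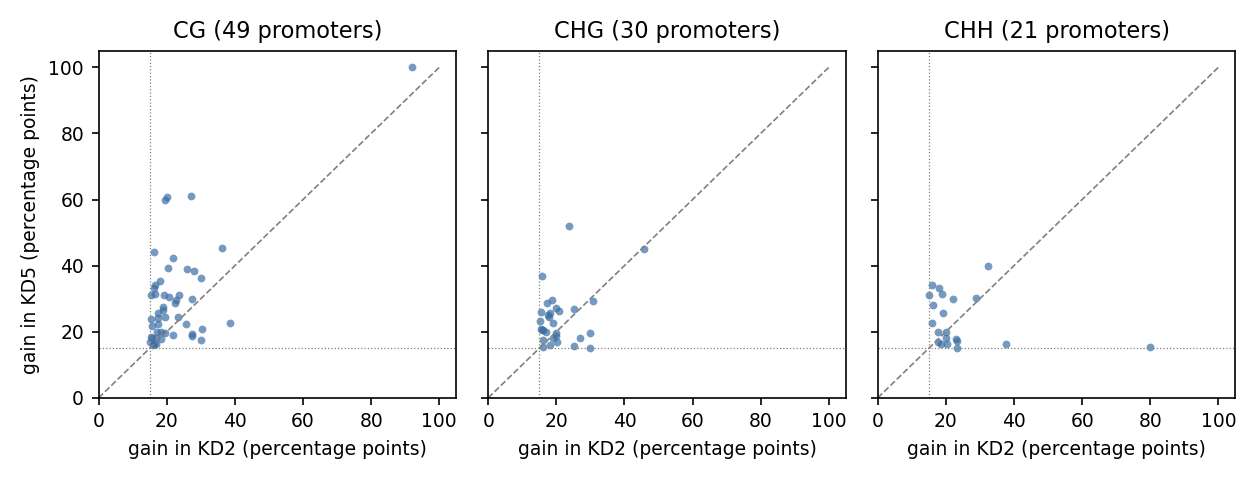
Methylation gain of each listed promoter in KD2 (horizontal axis) and KD5 (vertical axis), in percentage points, by context; 1 point is 1 promoter, the dashed line marks equal gains and the dotted lines mark 15 points. In CG, 38 of 49 points lie above the dashed line, and the point at 92 and 100 is Potri.001G149800.

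Among promoter genes, a negative logFC was the more common sign. Of the 83 genes, 55 had a negative logFC (66.3%, 55.1 to 76.3), and of the 524 transcribed region genes 254 did (48.5%, 44.1 to 52.8). With the 30 shared genes left out of both sets, 40 of 53 promoter genes (75.5%) and 239 of 494 transcribed region genes (48.4%) had a negative logFC (Fisher's exact test, two-sided, odds ratio of a positive logFC 0.305, p = 2.38e-04, adjusted p = 0.00238 over 10 comparisons). The 30 shared genes were split 15 to 15, and with them counted in each set the odds ratio was 0.479 (Fisher's exact test, adjusted p = 0.0301), and 0.432 in CG (Fisher's exact test, adjusted p = 0.0466). By context the difference passed the threshold in CG (75% against 44.7%, Fisher's exact test, adjusted p = 0.00685). It did not in CHG (71.4% against 46.7%, Fisher's exact test, adjusted p = 0.128) or CHH (66.7% against 47.9%, Fisher's exact test, adjusted p = 0.454). No context differed from another within a gene part (smallest adjusted p = 0.251, Fisher's exact test, CG against CHH in the transcribed region). The share of positive genes depended on the expression threshold: with an absolute logFC of at least 1, the positive genes rose from 33.7% to 52.3% of promoter genes and from 51.5% to 68.3% of transcribed region genes, while the odds ratio was 0.358 over 262 genes against 0.305 over 547 (Fisher's exact test, adjusted p = 0.0720). That cut keeps more of the weakly expressed genes, which mostly had a positive logFC. The median absolute logFC was 1.61 in the lowest and 0.81 in the highest logCPM quintile. At an FDR below 0.005, a level chosen after seeing the data, positive genes were 29.6% of promoter genes and 36.4% of transcribed region genes. The odds ratio was then 0.668 (Fisher's exact test, adjusted p = 1).

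The sign of the logFC also followed how strongly a gene was expressed. Among the 116 genes of the highest logCPM quintile, 8 had a positive logFC (6.90%, 3.02 to 13.1), against 81 of 116 in the lowest (69.8%, 60.6 to 78.0) and 88 of 115 in the next (76.5%, 67.7 to 83.9). The median logCPM was 3.96 for genes with a positive and 5.76 for genes with a negative logFC (two-sided permutation p = 1e-05 across genes, the smallest that 100000 resamples can give). Gene length, taken as the span of the gene coordinates with introns included, went with the sign as well. The 506 transcribed region genes with a single gene model had a median length of 4941 bases when the logFC was positive and 3647 bases when it was negative (two-sided permutation p = 1e-05). In the longest quintile, 7308 to 19168 bases, 78 of 101 genes had a positive logFC (77.2%, 67.8 to 85.0), against 38 of 102 in the shortest (37.3%, 27.9 to 47.4). Both comparisons were added after the data were seen.

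**Figure D3:**
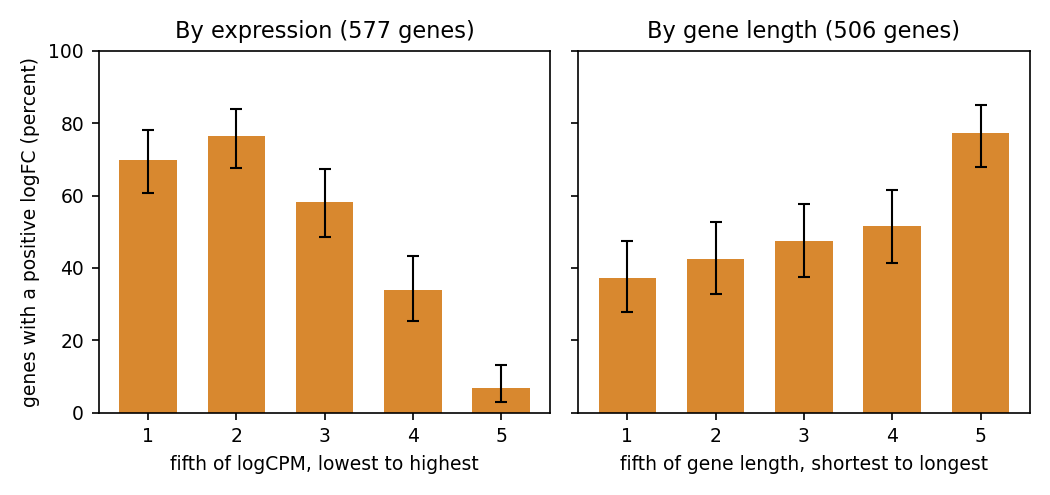
Percent of listed genes with a positive logFC (vertical axis) by quintile of logCPM over all 577 genes (left) and by quintile of gene length over 506 transcribed region genes (right); bars are shares and lines their exact 95% intervals. The share is 6.90% in the highest expression quintile and 77.2% in the longest quintile.

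The 12 promoter genes with the largest positive logFC were of mixed function. In the authors' deposited tables, logFC was 6.39 for a DNA-directed RNA polymerase family gene (Potri.017G063100), 4.88 for a GTP cyclohydrolase II gene of riboflavin synthesis (Potri.001G234900) and 4.24 for the mitochondrial carrier UCP5 (Potri.017G047800). Potri.017G063100 was weakly expressed, with a logCPM of 0.67 against a median of 4.81 over all listed genes. The window listed for Potri.017G063100 lies on chromosome 1 (32875691 to 32876720), not on the chromosome of its identifier. The UCP5 promoter (chromosome 17, 3996381 to 3998380) gained 16.3 points in KD2 and 44.1 points in KD5 in CG, per the authors' deposited tables. Next in the authors' deposited tables came a BED zinc finger gene with a hAT dimerisation domain (Potri.017G021800, 2.65), a DUF155 gene (Potri.008G092400, 2.44) and a tonoplast intrinsic protein gene (Potri.009G027200, 2.34). That aquaporin-family promoter gained 32.4 points in KD2 and 39.9 points in KD5 in CHH in the authors' deposited tables. The authors' deposited tables also listed the pentatricopeptide repeat genes PPR40 (Potri.008G108300, 2.0) and Potri.017G091600 (1.99), Potri.010G196400 (1.86), CSLD3 (1.79), the phosphatase gene PAP29 (Potri.014G109100, 1.5) and the aspartate aminotransferase gene ASP1 (Potri.016G133000, 1.48).

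The promoter genes with the most negative logFC included the chromatin remodeller DDM1, needed in Arabidopsis to maintain DNA methylation. For DDM1 (Potri.T120000) the authors' deposited tables gave a logFC of -1.46 and, for the window listed with it, a CHH gain of 17.7 points in KD2 and 20.0 points in KD5. That window is 544 bases long on chromosome 19 (15595460 to 15596003), while the identifier names no chromosome, so the window may belong to another gene. The lowest values in the authors' deposited tables were those of Potri.017G047500 (-3.11), Potri.005G221800 (-2.57) and the zinc-binding dehydrogenase gene Potri.001G391100 (-2.37). Potri.017G047500 and Potri.005G221800 were weakly expressed, with a logCPM of 0.33 and 0.40. The RAD-like MYB gene RL6 (Potri.002G035000) had -2.17 and a heavy metal transport and detoxification gene (Potri.010G024700) -1.88 in the authors' deposited tables. A lectin gene with an Apple-like domain (Potri.001G391200, -1.86), Potri.001G319300 (-1.79), a photosystem II 5 kD protein gene (Potri.009G052500, -1.52) and an RNA-binding protein gene (Potri.010G216800, -1.49) followed in the authors' deposited tables. The authors' deposited tables closed this set with Potri.010G121300 (-1.34) and the bZIP transcription factor gene BZIP61 (Potri.001G374200, -1.32). The window of Potri.005G221800 lies on chromosome 2, not on that of its identifier.

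Across promoters, the size of the gain was not related to the logFC. Spearman's rho lay between -0.23 (CG in KD2, permutation p = 0.103) and 0.28 (CHH in KD5, permutation p = 0.218), and each of the 6 relations had an adjusted p of 0.611 by permutation. Pearson's r was largest for CHH in KD5, at 0.46 (permutation p = 0.0353, adjusted 0.212), and was 0.35 without the 2 promoters farthest from the median gain. In CG, r was -0.16 in KD2 (permutation p = 0.218) and -0.13 in KD5 (permutation p = 0.346). These relations are across genes and are restricted to genes past both thresholds.

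In the transcribed region, the most negative logFC belonged to a carbonic anhydrase gene and the most positive to a gene without a description. In the authors' deposited tables the most negative logFC was -7.83, for carbonic anhydrase 1 (Potri.001G348900, chromosome 1, 35500037 to 35503657), listed in all 3 contexts with regions over coding sequence and 3' UTR. The authors' deposited tables then gave -3.84 for Potri.007G034000, -2.34 for a haloacid dehalogenase-like hydrolase gene (Potri.019G049000) and -1.99 for Potri.007G137000. The logCPM was 1.27 for carbonic anhydrase 1 and 0.18, the lowest of all listed genes, for Potri.007G034000. Photosystem II subunit R (PSBR, Potri.011G142200) had -1.96 and the MAK10 homologue Potri.T167600 -1.94 in the authors' deposited tables. The authors' deposited tables listed -1.84 for TAR2 (Potri.012G083300), a tryptophan aminotransferase of auxin synthesis, and -1.74 for a ribosomal L18p/L5e family gene (Potri.010G008200).

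The most positive transcribed region gene, Potri.017G018300, had a logFC of 6.72 in the authors' deposited tables. It was weakly expressed, with a logCPM of 0.93 against a median of 4.81 over the 577 listed genes. After UCP5, the authors' deposited tables listed the NB-ARC disease resistance gene Potri.001G433700 (4.13), Potri.002G040800 (3.91), a major facilitator gene (Potri.018G150700, 2.78) and the TIR-NBS-LRR gene Potri.017G132100 (2.77). A tetratricopeptide repeat gene (Potri.016G010100) had 2.54 and STN7 (Potri.010G129500), a thylakoid kinase of light harvesting proteins, had 2.47 in the authors' deposited tables.

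Of the 3 gene features counted, coding sequence was listed for the most genes. Introns were not counted and the lengths of the features were not taken into account, so these shares show no preference for coding sequence. Features listed beside each gene were read as those a region overlaps, since the coding segments listed left out segment 1 for 203 of the 271 CG genes with any. Coding sequence was listed for 271 of 388 CG genes (69.8%, 65.0 to 74.4), 111 of 178 CHG genes (62.4%, 54.8 to 69.5) and 76 of 123 CHH genes (61.8%, 52.6 to 70.4). The 3' UTR was listed for 114, 52 and 38 genes and the 5' UTR for 61, 25 and 21. None of the 3 features was listed for 53 CG genes (13.7%), 36 CHG genes (20.2%) and 21 CHH genes (17.1%). The share of positive logFC did not differ with any feature after adjustment over 12 comparisons (smallest adjusted p = 0.0895, Fisher's exact test, CG regions over coding sequence, 59.8% positive).

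Some genes were listed in more than 1 context. Overlaps are given without a test, since no list of all examined genes was used. In the transcribed region 136 of 524 genes (26.0%) were in 2 or 3 contexts and 29 in all 3. Of those 29, 19 had a positive and 10 a negative logFC. In promoters 16 of 83 genes (19.3%) were in 2 or 3 contexts. CG and CHG shared 88 transcribed region genes and 8 promoter genes, CG and CHH shared 59 and 5, and CHG and CHH shared 47 and 5. Genes listed for both promoter and transcribed region in the same context numbered 17 in CG, 9 in CHG and 6 in CHH.

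Genes with transcribed regions hypermethylated in all 3 contexts included a chromatin remodeller and an auxin synthesis gene. Besides carbonic anhydrase 1, TAR2, CSLD3, Potri.002G040800 and Potri.007G137000, the authors' deposited tables listed the BREVIS RADIX-like gene BRXL4 (Potri.018G064900, -1.55) and CHR11 (Potri.010G019800, -1.46), an ISWI-type remodeller. Positive values in the authors' deposited tables belonged to a TRAF-like gene (Potri.006G065300, 1.49), a 2-oxoglutarate-dependent oxygenase gene (Potri.009G091000, 1.32) and an ARM repeat gene (Potri.011G095700, 1.28). As the transcribed region tables give no gain, these genes were ranked by absolute logFC, a rule chosen after seeing the data.

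Listed genes lay on all 19 chromosomes, with most on chromosome 1. It held 71 of the 524 transcribed region genes (13.5%) and 24 of the 83 promoter windows (28.9%). Of those 24 windows, 18 belong to genes whose identifier names chromosome 1 and 6 to genes whose identifier names another. Chromosome 6 followed for the transcribed region with 44 genes (8.4%), and chromosome 8 for promoters with 7 windows (8.43%). The number of genes per chromosome was not used here, so no enrichment was tested.

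Genes for ribosomal proteins and translation mostly had a negative logFC, as did other highly expressed genes. Of 42 genes matched by this list, 38 had a negative logFC (90.5%, 77.4 to 97.3), against 47.9% of the other genes (Fisher's exact test, odds ratio of a positive logFC 0.0966, p = 2.45e-08, adjusted p = 3.44e-07 over 14 lists). A rubber elongation factor gene (Potri.005G025700) matched only by letters, and without it 90.2% of 41 genes were negative (Fisher's exact test, adjusted p = 6.56e-07). In the authors' deposited tables, examples were the ribosomal L18p/L5e gene (-1.74), a zinc-binding ribosomal protein gene (Potri.010G251500, -1.66) and an S26e gene (Potri.019G057000, -1.32), while an L28e gene (Potri.T165500) had 1.59. They were highly expressed, with a median logCPM of 7.27, and 30 of the 42 fell in the highest logCPM quintile, where 79 of the 86 genes outside the list also had a negative logFC (91.9%, 83.9 to 96.7). Within logCPM quintiles the 90.5% negative compared with 83.2% expected (permutation p = 0.141). Many ribosomal proteins have near-identical gene copies in poplar, and how reads were shared between copies is not given in the sources used here.

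Photosynthesis and chloroplast genes mostly had a negative logFC too, but missed the threshold after adjustment. A negative logFC was found for 9 of 10 (90%, 55.5 to 99.7, Fisher's exact test, p = 0.0206, adjusted p = 0.145). Within logCPM quintiles, a test added after the data were seen, 58.1% were expected (permutation p = 0.0247, adjusted 0.247 over 10 groups). The authors' deposited tables gave -1.96 for PSBR, -1.52 for the photosystem II 5 kD protein gene, -1.46 for the chlorophyll a/b binding protein gene CAB1 (Potri.005G239200) and -1.43 for HCF153 (Potri.001G022500). The exception among the 10 matched genes was TOC64-III (Potri.015G038600, 0.79 in the authors' deposited tables), a gene of the chloroplast outer membrane import machinery, named after the values were seen. The words of the list missed STN7, named above with a positive logFC, so the 10 are not all listed genes of photosynthesis.

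Disease resistance and receptor kinase genes and genes matched as transcription factors had more positive than negative logFC values, and neither list passed the threshold. Among disease resistance and receptor kinase genes 10 of 13 were positive and 3 negative (23.1% negative, 5.04 to 53.8, Fisher's exact test, adjusted p = 0.182), and all 13 were transcribed region genes. They were weakly expressed (median logCPM 2.74), and their logCPM quintiles gave an expected 71.5% positive against 76.9% found (permutation p = 0.762). Beyond those named above, the authors' deposited tables gave 2.25 for the NB-ARC gene Potri.001G428100 and 1.67 for the leucine-rich repeat kinase gene Potri.009G075400. Such genes often sit in clusters of close copies, and how reads were shared between copies is not given in the sources used here. Among 28 genes that matched the words of the transcription factor list 19 were positive and 9 negative (32.1% negative, 15.9 to 52.4, Fisher's exact test, adjusted p = 0.182). Examples in the authors' deposited tables were MYB62 (Potri.008G122100, 2.43), a C2H2-like zinc finger gene (Potri.002G143800, 2.40) and the MADS-box gene SEP1 (Potri.008G098400, 1.81). The 28 are not all transcription factors: PAP29 and 2 PAP2 phosphatase genes matched only by letters, and TIM10 (Potri.009G039600), RSZP21 (Potri.019G050600), an RNA-binding gene (Potri.008G033000) and several RING genes, named after the values were seen, matched as zinc finger proteins. Without the 3 letter matches 36% of 25 genes were negative (Fisher's exact test, adjusted p = 0.537), and within logCPM quintiles 44.0% of the 28 were expected to be (permutation p = 0.179).

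Genes matched by the meristem list had both signs. Of 7 genes, 3 were positive and 4 negative (57.1% negative, 18.4 to 90.1, Fisher's exact test, adjusted p = 1). The authors' deposited tables gave 1.40 for the boundary gene CUC3 (Potri.005G255900), -1.5 for HB31 (Potri.004G229600) and -1.0 for a KNAT6 homologue (Potri.015G079100). The list also held DMS3 (Potri.012G016000, 1.75 in the authors' deposited tables), which acts in RNA-directed DNA methylation and matched the list only through its full name. The other members were named after the values were seen. In the authors' deposited tables they were SPL7 (Potri.008G197000, 0.99), STM (Potri.004G004700, -0.87) and a further KNAT6 homologue (Potri.012G087100, -0.78). SPL7 matched through the word squamosa in its full name. The knotted-like genes STM and the KNAT6 homologues were all negative. With DMS3 and SPL7 set aside, CUC3 was still positive, so the mixed sign does not come from those matches alone.

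Chromatin genes numbered 5, of which 3 were positive and 2 negative (Fisher's exact test, adjusted p = 1). In the authors' deposited tables those with the largest absolute logFC were a SET domain gene (Potri.004G135700, 1.89), DDM1, CHR11 and the Polycomb gene EMF2 (Potri.003G150400, 1.18). DDM1 was the only gene of the DNA methylation and demethylation list. In the cell wall list 4 of 5 were negative (80%, 28.4 to 99.5, Fisher's exact test, adjusted p = 0.981). Its members in the authors' deposited tables included CESA7 (Potri.006G181900, -1.32), a cellulose synthase of secondary walls, a pectin lyase-like gene (Potri.006G122000, -0.94), XTH32 (Potri.006G122900, -0.84), and CSLD3. Cell cycle and DNA replication genes were split 4 positive to 3 negative (Fisher's exact test, adjusted p = 1). The authors' deposited tables gave 2.23 for the DNA polymerase gene REV1 (Potri.009G094400), -0.93 for the cyclin gene RCY1 (Potri.008G043600), 0.87 for the kinesin gene ZWI (Potri.011G146700) and 0.86 for a DNA polymerase V family gene (Potri.009G079900). Transport genes were split 4 to 4 (Fisher's exact test, adjusted p = 1). They included in the authors' deposited tables the phosphate transporter PHT4 family gene ANTR1 (Potri.001G249800, -1.06), a nucleotide/sugar transporter gene (Potri.006G278700, 1.02), the vacuolar cation channel TPC1 (Potri.013G131100, 0.99) and the mechanosensitive channel MSL10 (Potri.006G222500, 0.98).

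Seasonal and hormone lists were nearly empty. Flowering, clock and photoperiod genes were SEP1 and the clock gene LHY (Potri.002G180800, -0.80 in the authors' deposited tables). Single genes represented cytokinin and related signalling (the response regulator ARR12, Potri.018G111300, 1.31 in the authors' deposited tables) and temperature and dehydration stress (an Hsp70 gene, Potri.004G016700, 0.94 in the authors' deposited tables). The transposon-related list matched 1 RNA-binding protein gene (Potri.008G033000, -1.12 in the authors' deposited tables) through a word of its description. Its words missed Potri.017G021800, named above (2.65), and Potri.017G022500 (1.35 in the authors' deposited tables). Both are annotated with a hAT dimerisation domain, and the miss was found after the values were seen. No gene matched the flavonoid, gibberellin, abscisic acid or auxin lists as worded. These lists missed TAR2 of auxin synthesis and HAI3 (Potri.001G092100, -1.25 in the authors' deposited tables), annotated as an ABA-induced phosphatase gene and found after the values were seen.

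**Figure D4:**
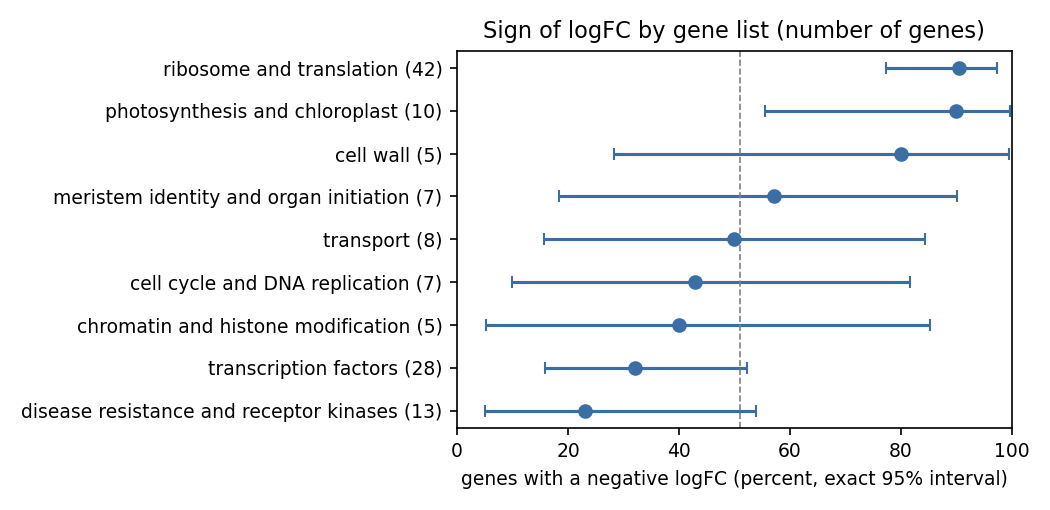
Percent of genes with a negative logFC (horizontal axis) for each list of at least 5 genes, with the number of genes in brackets; points are shares, lines are exact 95% intervals and the dashed line is the share over all 577 genes, 51.0%. The ribosome and translation list, at 90.5%, has an interval of 77.4 to 97.3.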

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

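No paired analysis was possible because each genotype gave 1 library. Of 208 alternative values over 64 results, 159 kept their direction and their side of the threshold, or stayed within their interval or 1.5 times the count. Some of the 159 could not change, since a gene has 1 region per table or the filter left the genes of that result untouched. The count is therefore not a measure of stability. Causes of the changes were not tested, beyond the smaller number of genes where a filter left fewer. The FDR level, the chromosome filter, the removal of gains of 80 points or more and the lists without letter matches were chosen after seeing the data. Unknown sequencing depth limits every gain.

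Requiring a gain of at least 1.5 times the smallest in both lines left 11 promoters in CG, 4 in CHG and 2 in CHH, 17 genes in all. By construction the median gain then rose, to 27.4 points in KD2 and 36.2 in KD5 for CG, 28.0 and 37.2 for CHG, and 30.7 and 35.1 for CHH. The CG minus CHG difference turned to -0.66 points in KD2 and -0.98 in KD5, neither past the threshold before or after. The gain was larger in KD5 at 90.9% of the CG promoters left, and 100% of the 2 CHH genes had a positive logFC. The odds ratio of a positive logFC in promoter against transcribed region was 0.378 (CG alone 0.346) but no longer passed the threshold. CG against CHG promoters turned to 1.13. Means in place of medians gave 22.6 points for CG, 20.9 for CHG and 24.0 for CHH in KD2, outside the bootstrap intervals of the medians.

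With an absolute logFC of at least 1, the positive share was 51.9% for CG promoters and 52.3% for all promoters. In the transcribed region it was 71.1% in CG, 66.3% in CHG and 68.3% in all. The promoter against transcribed region odds ratio was 0.358 (CG alone 0.263), short of the threshold. The sign of the non-significant difference from other genes turned for the chromatin list (40% negative), the meristem list (33.3%) and the transport list (50%). At an FDR below 0.005 the positive share of transcribed region genes was 39.3% in CG, 43.5% in CHG, 33.3% in CHH and 36.4% in all. The promoter against transcribed region odds ratio was then 0.668 (CG alone 0.395), short of the threshold, and 1.33 in CHH. Between promoter contexts it turned to 1.82 for CG against CHG and 0.6 for CHG against CHH.

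With promoters on the chromosome of their identifier, Spearman's rho between lines was 0.39 in CG and -0.51 in CHH, both past the threshold by permutation, and -0.15 in CHG. The odds ratio for CG against CHH promoters was 1.01 there, and 1.06 over all promoters with shared genes counted in each. Counting them in each moved the promoter against transcribed region odds ratio to 0.479 (CG alone 0.432), still past the threshold. Without the 2 farthest promoters rho between lines was 0.31 in CG and -0.19 in CHH, and without gains of 80 points or more 0.29 and -0.30, both of the latter short of the threshold. Lists without letter matches gave 90.2% negative for ribosome and translation and 36% for transcription factors. With absolute logFC, rho with the gain changed sign for CG in KD5 (0.14), CHG in KD2 (-0.37), CHG in KD5 (-0.050) and CHH in KD2 (-0.11), all short of the threshold. With Arabidopsis loci alone the flowering list kept 1 gene, 100% negative. A stricter p of the region, expression per line and overlap of regions between contexts were not run, since the tables used here hold no such values.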

Other observations

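The word groups, their test within logCPM quintiles and the values on promoter windows, columns and effect sizes were chosen only after the results were seen. Tests of explanations for the sign patterns were written down before their results.

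Pentatricopeptide repeat genes, which encode RNA-binding proteins of mitochondria and chloroplasts, all had a positive logFC. There were 7, in promoter or transcribed region tables, with a median logFC of 1.99 and 0 negative (0% negative, exact interval 0 to 41.0). Against all other genes this gave p = 0.00657 by Fisher's exact test and 0.0526 after adjustment over 8 word groups. The genes were weakly expressed, with a median logCPM of 2.81, and their logCPM quintiles gave an expected 30.9% negative (permutation p = 0.0987). In the authors' deposited tables the largest were Potri.006G106400 (2.34) and Potri.018G143800 (2.13), besides PPR40 and Potri.017G091600. Genes with RNA-binding annotations were negative in 14 of 19 cases (73.7%, exact interval 48.8 to 90.9, Fisher's exact test, adjusted p = 0.241). Protein kinase genes were positive in 8 of 12 cases (Fisher's exact test, adjusted p = 0.486), and ubiquitin and RING genes in 9 of 17 (adjusted p = 0.924).

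Among the listed genes, absolute logFC was larger in those weakly expressed. The median was 1.61 in the lowest and 0.81 in the highest logCPM quintile, and the smallest listed value fell from 0.99 to 0.62. All listed genes passed an FDR below 0.05, which needs a larger logFC where counts are low. The difference therefore says nothing about genes that were not listed.

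Ribosome and translation genes mostly had a negative logFC, and expression level is a candidate explanation that remains. Within logCPM quintiles the list's 90.5% negative compared with 83.2% expected (permutation p = 0.141), so most of the excess over the other genes (47.9%) went with expression level. Within 9 cells of logCPM by gene length it was 89.2% against 87.5% (permutation p = 0.769). Gene length alone did not account for it, since within length quintiles the expected share was 59.1% (permutation p = 8.0e-05). A trend of sign with expression can come from normalization of the expression libraries or from the knockdown itself, and the tables used here hold no library values to separate these, so a biological explanation was not tested.

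Among genes listed for the promoter alone, the excess of negative logFC was not removed by expression level. Within logCPM quintiles, 75.5% of these 53 genes were negative against 50.8% expected (permutation p = 3.0e-05). Without ribosome and translation genes the shares were 74% of promoter and 44.8% of transcribed region genes (Fisher's exact test, p = 8.74e-05). The 30 shared genes, split 15 to 15, were left out of both tests, so the full set of 83 promoter genes was not checked within quintiles. Gene length remains open: the 36.1% of promoter genes with a length are the 30 shared genes, which the comparison leaves out, so 0 of the 53 compared have one. At an absolute logFC of at least 1 the odds ratio was 0.358 over 262 genes, against 0.305 over 547, and at an FDR below 0.005 it was 0.668 over 174 genes, neither past the threshold. An effect of promoter methylation on expression is a hypothesis that may explain it. It was not tested directly, since the direction of logFC is not stated and unmethylated genes were not used here. Across listed promoters the size of the gain was not related to the logFC (permutation of Spearman's rho, adjusted p = 0.611 in each of 6 relations). Only genes past both thresholds were listed, so that result cannot decide the question.

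Long genes more often had a positive logFC, and neither expression level nor the ribosome list accounted for it. Within logCPM quintiles the geometric mean length of positive genes was 4936 bases against 4289 expected (permutation p = 1e-05, the smallest that 100000 resamples can give). Without the ribosome list the medians were 5046 and 3901 bases (permutation p = 0.0001). The length is the span of the gene coordinates, introns included, and transcript length was not used. Length-dependent recovery of RNA between libraries could give such a trend if transcript length follows that span, and so could the knockdown. Both were left untested, as no expression library was used here.

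Among the 83 promoter windows, 72 span 2000 bases, and the 28 with gene coordinates on the same chromosome all directly adjoin the gene. In 9 windows the chromosome is not that of the gene identifier, and all 9 are shorter, 299 to 1097 bases, as are 2 of the other 74 (Fisher's exact test, p = 1.67e-10). Which genes these windows, and with them their gains, belong to was not settled. For 2 of these 9 genes the transcribed region tables place the gene on the chromosome of its identifier, so those 2 windows do not adjoin their gene. All 9 stay among the 83 promoter genes. None of 517 transcribed region genes with a chromosome in the identifier was listed on another. In the transcribed region tables, a further set of unexplained coordinate columns was filled for 193 of 388 CG, 135 of 178 CHG and 103 of 123 CHH genes, and was not used here. Coordinates of more than 1 gene model stood beside 16 CG, 4 CHG and 2 CHH genes.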
